A study of Mus musculus with 4 samples.

How the data were processed

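Gene expression was measured on Affymetrix Mouse Gene ST 2.1 arrays in liver RNA of male mice that were wild type (WT) or knockout (KO) for Nrg4. All mice ate a diet that produces non-alcoholic steatohepatitis (NASH) for 20 weeks, from 3 months of age, and livers were taken from fed animals. Each array held a pool of liver RNA, with 2 pools per genotype. The number of animals in a pool is not given in the sources used here. Per the labels' protocols, 400 ng of total RNA was labelled with biotin using an Affymetrix whole-transcript kit.

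The values used are the deposited log2 expression values of 41345 probe sets on the 4 arrays. Per the submitters' processing notes, oligo, RMA and limma were used; their versions, the order of steps, the genome build and the annotation are not given in the sources used here. RMA is a procedure that corrects background, equalises the distributions of the arrays and summarises the probes of a probe set on a log2 scale. The array medians were 0.52 and 0.56 in the WT pools and 0.64 and 0.53 in the KO pools, and the values ran from -1.12 to 11.9. The zero point of this log2 scale is therefore not that of the usual RMA output and stays unknown, so levels are comparable between arrays and not with other studies. The values were not centred per gene, and differences are read as KO minus WT on the log2 scale. No detection calls were used here, and dim values may lie at the low end of the scale, where folds are compressed. No scan date or slide was used here, so no batch could be tested. The number of arrays limits the precision of every value.

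Probe sets were named through the platform annotation. Of the probe sets, 23521 were paired with 1 gene symbol, 1814 with several and 16010 with none, and probe sets with several symbols or none were left out of the gene tests. Entrez identifiers of 23328 single-symbol probe sets were found in the RefSeq gene table of assembly GRCm38.p6, which changed no symbol. For the 1082 genes with several probe sets, the one with the highest mean over the 4 arrays was used, which left 22180 genes. Genes with a mean at or above the median of all probe sets in the table (0.54) were tested, 12458 in all. Genes of large families (Mup, Cyp2c, Cyp4a, Serpina1, Sult and immunoglobulin genes) share sequence, so their probe sets may measure relatives too.

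KO was compared with WT by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, statmod 1.5.0 for the robust option), with no covariate, 2 residual and 3.67 prior degrees of freedom, and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Because the samples are pools, p-values measure the spread between 2 pools of each genotype. An exact permutation of 2 pools against 2 cannot reach 0.05, since chance alone separates the groups in 33.3% of genes. The level of Nrg4 was read from a fit of all 22180 genes, since it was expected to be dim. Fixed before the data were examined were 41 gene lists for liver processes, liver cell types and tissues that a liver sample can contain. The 38 lists with at least 5 tested members were compared with the other genes by limma's camera with a preset correlation of 0.01, adjusted over the lists. Beside it stand camera with an estimated correlation, fry, and the number of members past the threshold over all genes and adjusted over the list alone. Lists of neutrophil, pancreatic acinar and erythroid markers had 3, 4 and 3 tested members and were not tested.

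Genes named in the text were chosen by a rule fixed before the data were examined. They are Nrg4, the 12 genes with the largest increase and the 12 with the largest decrease whose pools did not overlap, the 4 members of each list with the smallest p, any list member past the threshold, and Cflar, Ripk3, Mlkl, Col1a1, Timp1, Acta2, Egfr, Erbb3 and Erbb4. The 12 were taken from called genes and filled up from genes at an unadjusted p under 0.01, leaving out clone, predicted and small RNA names. Other genes are said to be chosen after their values were seen.

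The procedure was tested on simulated data, with 200 of 12458 genes changed in each of 20 simulations. Variances were drawn at random from the prior distribution that limma fitted to the KO and WT comparison. A gene's own variance and intensity did not enter, so the shares below may not hold where variance follows intensity. limma called 2.84% of genes changed by 1 on the log2 scale, 74.7% of those changed by 2 and 94.0% of those changed by 3, with a mean of 5.45 false calls. With a shift of 0.5 added to the matrix list, camera with the preset correlation called it in 20 of 20 simulations and camera with an estimated correlation in 0 of 20. With no shift, a mean of 0.05 of 38 lists was called per simulation. Genes were drawn independently in these simulations, so list members were not correlated. In the data the estimated correlation was 0.02 in the matrix list, 0.10 in the male-biased list and 0.23 in the gluconeogenesis list. The simulations therefore do not show how often correlated lists are called without a shift. Alternatives were the filter on dim genes, the normalization, the variance model, the threshold, the probe sets per gene, the set test, the replicate number as a block, and leaving out each pool. The replicate numbers name pools and are not stated to mark a shared day or litter, so they were not treated as pairs.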

Results

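Liver RNA pools of WT and Nrg4 KO mice on the NASH diet were compared, with 2 pools per genotype. Nrg4 (neuregulin 4) is a secreted ligand of the epidermal growth factor family, and the comparison asks how its loss alters gene expression in a liver under a diet that causes steatohepatitis. Across the 12458 tested genes, the WT pools correlated with each other at r = 0.979 and the KO pools at 0.975, and the 4 correlations between genotypes lay between 0.966 and 0.973. These are correlations across genes, which are not independent replicates.

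Nrg4 expression was lower in the KO livers. Its log2 level was 2.42 ± 0.17 (SD, n = 2) in WT and 0.93 in both KO pools. The difference was -1.49 ± 0.20 (SE; limma, adjusted p = 0.182 over all 22180 genes), and its unadjusted p as the 1 gene set in advance lay under 0.05. The KO level lay 0.39 above the median of all probe sets, and in KO pool 1 the same value was shared by 301 probe sets, so no fold is given. Whether the probe set lies in the disrupted part of the gene is not given in the sources used here.

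The KO livers expressed less Slco1a1, an organic anion transporter of the hepatocyte membrane, and more Sprr1a, a small proline-rich protein of epithelia. Slco1a1 fell from 7.12 ± 0.19 to 1.09 ± 0.47 (SD, n = 2 each), a log2 difference of -6.03 ± 0.28 (SE; adjusted p = 0.0153). Also lower were Sult1e1, the oestrogen sulfotransferase, at -3.68 ± 0.28, and Clec2h, a C-type lectin, at -2.81 ± 0.21 (adjusted p = 0.0378 for both). Higher were Sprr1a at 3.00 ± 0.20, Rragd, a GTPase of the amino acid-sensing Rag complex, at 2.67 ± 0.20, and Sytl5, a synaptotagmin-like protein, at 2.48 ± 0.19 (adjusted p = 0.0378 for each). The KO means of Slco1a1, Sult1e1 and Clec2h lay 0.55, 0.22 and 0.51 above the table median, the WT mean of Sprr1a 0.58 above it and that of Sytl5 0.52 below it, so no fold is given for them. Rragd was 6.34-fold higher. These 3 genes higher and 3 lower in KO were the ones past the threshold by limma. With a variance that follows intensity, the same test called 136 genes, 49 higher and 87 lower, which included all 6. At an unadjusted p under 0.05 there were 794 higher and 488 lower, against 622.9 expected by chance in both directions. That share of higher genes was 61.9% as deposited and 46.4% with arrays centred on their medians. Without any 1 of the 4 pools, no gene passed the adjusted threshold by limma, and 906 to 1314 genes had an unadjusted p under 0.05.

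The other genes with the largest differences did not pass the adjusted threshold with the preset variance model and are given as values with their SE. With a variance that follows intensity, limma called 22 of the 24 genes with the largest differences, all but Zfp984 and the kappa chain segment. Zbtb16 also passed with no filter on dim genes (adjusted p = 0.0408) and with a stricter one (0.0191), and Cyp2c54 with arrays centred on their medians (0.0434). On the lower side were Mup21, a major urinary protein, at -3.65 ± 0.91, Serpina4-ps1 at -3.52 ± 0.60, Cyp2c54 at -3.52 ± 0.34 and Serpina1e at -3.05 ± 0.61. Acot1, an acyl-CoA thioesterase, differed by -2.93 ± 0.40, Bmp10 by -2.66 ± 0.30, Cyp4a12b by -2.63 ± 0.52, Hsd3b5 by -2.61 ± 0.33 and Zbtb16 by -2.38 ± 0.20. On the higher side were Cib3 at 2.75 ± 0.39, Pls1, an actin-bundling protein, at 2.70 ± 0.35, Zfp984 at 2.11 ± 0.55, Plet1 at 2.09 ± 0.36 and Elapor1 at 2.07 ± 0.23. Dpt, the matrix protein dermatopontin, was at 1.97 ± 0.24 and Mmp7, a matrix metalloproteinase, at 1.95 ± 0.35. A kappa and a heavy chain immunoglobulin variable segment were at 2.17 ± 0.50 and 1.99 ± 0.36. Mup21 and Serpina4-ps1 were further down in KO pool 1 (0.46 and 1.11) than in KO pool 2 (3.43 and 3.02). Without KO pool 1 Mup21 was at -2.17, without WT pool 2 Zfp984 was at 1.25, and Mmp7 was at 1.05 as the mean of its probe sets. Relative to the table median, the WT means of Cib3, Elapor1 and Mmp7 lay at -0.05, -0.03 and 0.02. The KO means of Bmp10 and Hsd3b5 lay at 0.06 and 0.09. Differences that reach such levels may be compressed.

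**Figure D1:**
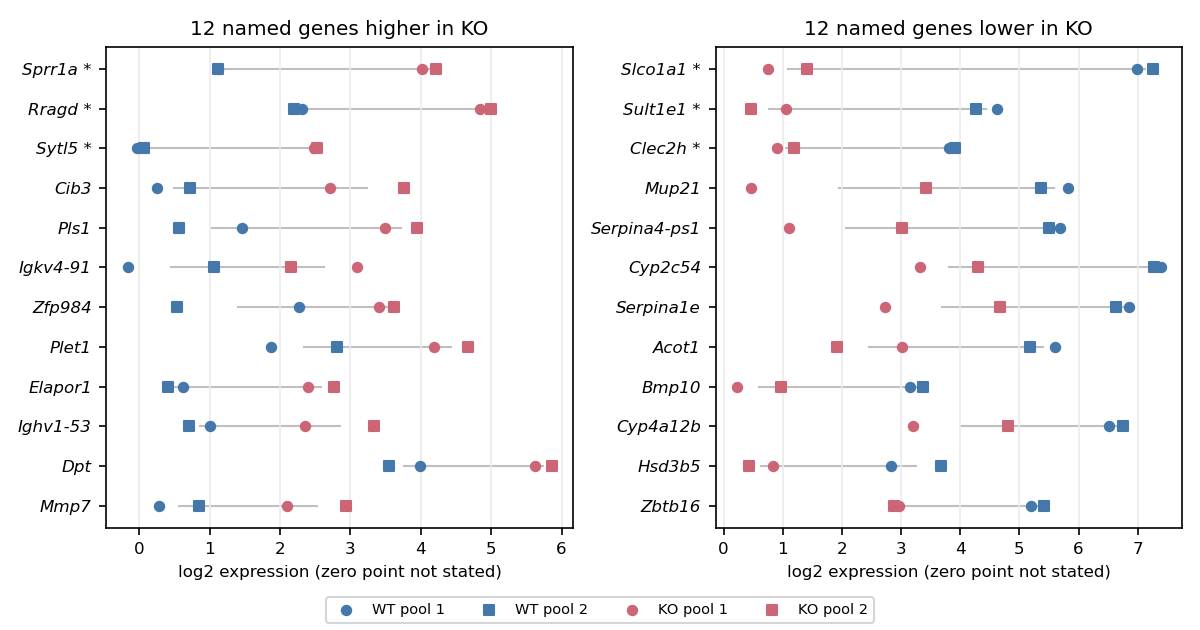
Log2 expression (x axis) of the 12 genes with the largest increase and the 12 with the largest decrease in KO, with 1 point per pool and a grey line between the group means. An asterisk marks the 6 genes past an adjusted p of 0.05, and Slco1a1 spans the widest gap, from 7.12 in WT to 1.09 in KO.

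Genes that male mouse livers express more than female ones fell as a group in the KO livers. Of 21 measured members, 19 were lower in KO, with a median difference of -0.92 (camera, adjusted p = 2.1e-15; adjusted p = 0.227 with an estimated correlation). Slco1a1 was the 1 member past the threshold over all genes, and 12 members were lower when adjusted over the list alone. Beside Slco1a1 these include Hsd3b5, a hydroxysteroid dehydrogenase, Cyp4a12a (-1.87 ± 0.24 SE), a fatty acid hydroxylase, and Susd4 (-1.60 ± 0.24). The list mean relative to WT was -1.75 in KO pool 1 and -1.27 in KO pool 2. The 17 measured female-biased genes gave a median of 0.13, and the list did not pass (adjusted p = 0.748). Among them, 11 members were above 0 and 6 below, and 1 was higher and 2 lower when adjusted over the list alone. Cyp2b9 was at 1.48 ± 0.28 and Cyp2b13 at 0.93 ± 0.27, while Sult1e1 was at -3.68 ± 0.28. The list of hepatocyte secreted proteins and transcription factors was also lower, with a median of -0.25 (adjusted p = 0.361 with an estimated correlation), or -0.09 without KO pool 1. Among the members of all lists, Slco1a1 and Sult1e1 were the ones past the threshold over all genes. With a variance that follows intensity, limma called 11 male-biased, 9 cytochrome P450, 6 amino acid and 3 hepatocyte list members as lower and 3 extracellular matrix members as higher.

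Genes of the extracellular matrix rose in the KO livers. Of 35 measured members, 33 were higher in KO, with a median of 0.56 (camera, adjusted p = 1.55e-09; adjusted p = 0.227 with an estimated correlation). Of the members, 8 were higher when adjusted over the list alone. The members with the smallest p were Dpt, Lum (1.26 ± 0.21 SE), a collagen-binding proteoglycan, Col15a1 (1.01 ± 0.20) and the basement membrane collagen Col4a2 (0.87 ± 0.20). Col1a1, a chain of type I collagen, was at 0.71 ± 0.19. Matrix proteases and inhibitors rose by a median of 0.57 over 16 members (adjusted p = 1.75e-05; adjusted p = 0.227 with an estimated correlation). Plat, the tissue plasminogen activator, was at 1.22 ± 0.21, Mmp14 at 0.70 ± 0.20, Mmp2 at 0.84 ± 0.27 and Timp1 at 0.34 ± 0.22, the last at 0.14 without WT pool 1 and 0.54 without WT pool 2. The hepatocyte list stood at -0.25 in the same pools.

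Markers of stellate cells, the pericytes of the liver, did not pass as a list (median 0.08 over 18 members, adjusted p = 0.066). Inside the list, Pdgfra (1.67 ± 0.29 SE), Pdgfrb (1.14 ± 0.20) and Cygb (0.88 ± 0.19) were higher when adjusted over the list alone. Acta2, the smooth muscle actin of myofibroblasts, differed by 0.01 ± 0.20, a sign that turned when arrays were quantile normalized or centred on their medians, without WT pool 1 (-0.11) and without KO pool 1 (-0.08). The TGF-beta pathway list had a median of 0.16 (adjusted p = 0.0565), with Tgfbr2 at 0.76 ± 0.20 and Tgfb1 at 0.55 ± 0.21. Both lists passed with no filter on dim genes and with a stricter one, with adjusted p between 0.0102 and 0.0389. The TGF-beta list also passed without WT pool 2 (median 0.29, adjusted p = 0.0136) and without KO pool 1 (median 0.31, adjusted p = 0.0194), and the stellate list without WT pool 1 (median 0.22, adjusted p = 0.0312).

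Markers of monocyte-derived and lipid-associated macrophages rose in the KO livers. Of 20 measured members, 18 were higher, with a median of 0.58 (camera, adjusted p = 8.65e-07; adjusted p = 0.227 with an estimated correlation), and 9 were higher when adjusted over the list alone. The tetraspanin Cd63 was at 0.98 ± 0.20 SE, the lipid receptor Trem2 at 1.30 ± 0.29, Ms4a7 at 1.28 ± 0.30 and the chemokine receptor Cx3cr1 at 1.59 ± 0.37. Cytokines and chemokines rose by a median of 0.31 over 25 members (adjusted p = 0.00298; adjusted p = 0.473 with an estimated correlation), a call lost without KO pool 2 (adjusted p = 0.101). Cxcl16 was at 1.204 ± 0.21 and Tnf at 1.01 ± 0.25. The list of dendritic cell and MHC class II genes rose by a median of 0.57 over 9 members (adjusted p = 0.0122; adjusted p = 0.473 with an estimated correlation), with 3 higher when adjusted over the list alone and H2-Ab1 at 0.93 ± 0.19. That call was lost without WT pool 1 (median 0.13, adjusted p = 0.31) and without KO pool 1 (median 0.71, adjusted p = 0.0988). With no filter on dim genes the medians of the cytokine and MHC class II lists were 0.20 and 0.26. T and NK cell markers had a median of -0.02 (adjusted p = 0.809) and endothelial markers one of 0.09 (adjusted p = 0.444), beside a hepatocyte list at -0.25. Of 23 T and NK cell markers 12 were tested, 5 of them above 0 and 7 below. Cd3g was at 1.07 ± 0.34, or 0.60 without KO pool 2, and Cd4 at -0.40 ± 0.20. Relative to the table median, the KO mean of Cd4 lay at -0.07 and the WT mean of Cd8a at -0.05. Changes at such levels may not be seen.

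Cholangiocyte and ductular markers rose by a median of 0.83 over 12 members (camera, adjusted p = 9.76e-05; adjusted p = 0.227 with an estimated correlation). The adhesion protein Cdh1 was at 1.62 ± 0.28 SE, Mmp7 at 1.95 ± 0.35 and Cd24a at 1.31 ± 0.24, and these 3 were higher when adjusted over the list alone. As means of their probe sets Cdh1 was at 0.88 and Mmp7 at 1.05. The median was 0.51 without WT pool 2 and 0.53 without KO pool 2, and the list passed in both cases. Krt19, a bile duct keratin chosen after its value was seen, differed by -0.06, with a KO level 0.19 above the table median. Oncofetal and tumour markers rose by a median of 0.83 over 12 members (adjusted p = 3.1e-05; adjusted p = 0.227 with an estimated correlation). Those that led the list were S100a11 (1.201 ± 0.20), Ly6d (1.43 ± 0.27), Sox4 (1.31 ± 0.25) and Anxa2 (1.09 ± 0.21), among 6 members higher when adjusted over the list alone, and epithelial cells and leukocytes also express them. As the mean of its probe sets Sox4 was at 0.69. With no filter on dim genes the list median was 0.28. The fetal genes Igf2 and Gpc3, chosen after their values were seen, differed by 0.20 and 0.09 at levels near the table median. A probe set shared by H19 and Mir675, left out of the gene tests and also chosen after its value was seen, differed by 1.31. It did not pass over all probe sets (limma, adjusted p = 0.458), and its WT values were 0.31 and 0.46. The hepatocyte list stood at -0.25 in the same pools.

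**Figure D2:**
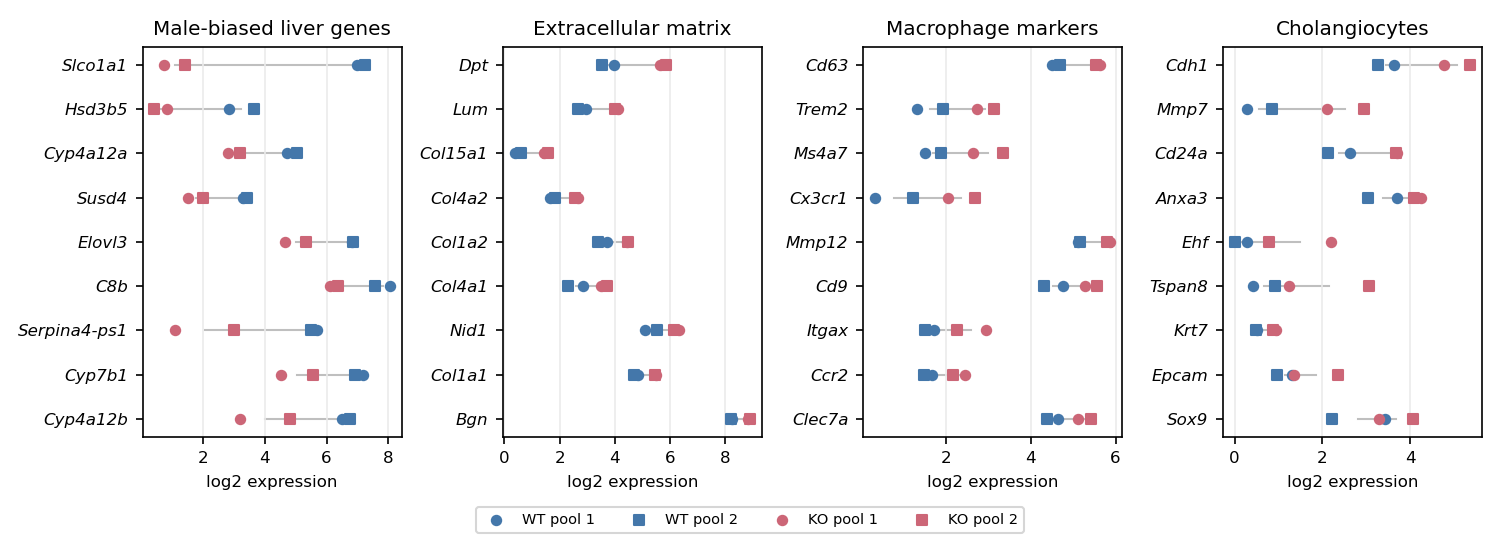
Log2 expression (x axis) of the 9 members with the smallest unadjusted p of 4 gene lists, with 1 point per pool and a grey line between the group means. These members were picked for their difference; Dpt and Lum lie higher in both KO pools and Slco1a1 and Hsd3b5 lower.

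Several lists of hepatocyte metabolism fell in the KO livers, while those of de novo lipogenesis and of lipid droplets and uptake did not pass camera. In the same pools the hepatocyte list stood at -0.25, the matrix list at 0.56, the macrophage list at 0.58 and the ductular list at 0.83. Amino acid catabolism and the urea cycle fell by a median of 0.39 over 37 members, 33 of them lower (camera, adjusted p = 1.18e-09; adjusted p = 0.284 with an estimated correlation). Ahcy, which hydrolyses S-adenosylhomocysteine, was at -0.96 ± 0.24 SE, or -0.08 as the mean of its probe sets, and the histidine ammonia-lyase Hal at -0.73 ± 0.19. Cytochrome P450 and phase II genes fell by a median of 0.28 over 35 members (adjusted p = 1.06e-05; adjusted p = 0.403 with an estimated correlation), with Cyp2c54, Cyp2c37 (-1.47 ± 0.26), Cyp2c50 (-1.44 ± 0.26) and Cyp2f2 (-0.92 ± 0.19) among 5 lower when adjusted over the list alone. That median was -0.15 without KO pool 1 and -0.16 with no filter on dim genes. Fatty acid oxidation and PPAR-alpha targets fell by a median of 0.19 over 35 members (adjusted p = 1.69e-05; adjusted p = 0.227 with an estimated correlation), led by Acot1 and Cyp4a14 (-1.26 ± 0.24). Bile acid genes fell by a median of 0.22 over 25 members (adjusted p = 0.00107; adjusted p = 0.48 with an estimated correlation). Of these members 16 were lower and 9 higher, and the bootstrap interval of the median over genes was -0.37 to 0.01. Without KO pool 1 the bile acid median was -0.14. The leading members Slco1a1 and Cyp7b1 (-2.01 ± 0.37), an oxysterol hydroxylase, are also on the male-biased list.

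Genes of gluconeogenesis and fasting fell by a median of 0.29 over 25 members (camera, adjusted p = 0.00289; adjusted p = 0.48 with an estimated correlation), with Got1 at -0.92 ± 0.24 SE and Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, at -0.63 ± 0.20. The hepatocyte list fell by a median of 0.25 over 39 members (adjusted p = 0.000112; adjusted p = 0.361 with an estimated correlation), with Foxa3 at -0.85 ± 0.24 and Onecut1 at -0.67 ± 0.19. Its median was -0.09 without KO pool 1 and -0.16 without WT pool 1, and the list passed in both cases. Mitochondrial respiratory chain genes fell by a median of 0.14 over 45 members (adjusted p = 0.0017; adjusted p = 0.228 with an estimated correlation), or 0.07 with quantile normalization. Cholesterol synthesis fell by a median of 0.15 over 20 members, led by Ebp at -0.69 ± 0.19. Of these members 13 were lower and 7 higher, and the bootstrap interval of the median over genes was -0.46 to 0.02. The list was called by camera (adjusted p = 0.0188; adjusted p = 0.403 with an estimated correlation). That call was lost without WT pool 2 (adjusted p = 0.154), without KO pool 2 (median -0.28, adjusted p = 0.076) and with a stricter filter on dim genes (median -0.12, adjusted p = 0.0708), and the median was -0.26 without WT pool 1 and -0.25 without KO pool 1. No member of these 4 lists passed the threshold adjusted over its list alone, while a variance that follows intensity called 3 hepatocyte and 2 gluconeogenesis members by limma.

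Genes of the endoplasmic reticulum stress and integrated stress response fell in the KO livers. Of 27 measured members, 24 were lower, with a median of -0.35 (camera, adjusted p = 1.06e-05, or 0.227 with an estimated correlation). Of the 18 lists called by camera, this was the 1 that fry called too (fry, adjusted p = 0.0197). By fry the male-biased, matrix and macrophage lists were at an adjusted p of 0.061 and the hepatocyte list at 0.171. No single member passed with the preset variance model, even adjusted over the list alone, while a variance that follows intensity called Herpud1 (adjusted p = 0.0379) and Dnajb9 (0.0418) by limma. The hepatocyte list stood at -0.25 in the same pools, the matrix list at 0.56 and the macrophage list at 0.58. The co-chaperone Dnajb9 was at -0.80 ± 0.20 SE, the pseudokinase Trib3 at -0.83 ± 0.29, Herpud1 at -0.50 ± 0.19 and Asns, the asparagine synthetase, at -0.71 ± 0.31. Without 1 pool Asns lay between -1.08 and -0.34, and Trib3 was at -0.51 without WT pool 2. The list mean relative to WT was -0.32 in KO pool 1 and -0.30 in KO pool 2.

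Genes of apoptosis and necroptosis did not pass camera as a list, and their median took either sign when a KO pool was left out (0.13 without KO pool 1 and -0.13 without KO pool 2). The median over 32 members was 0.02, with a bootstrap 95% interval over genes of -0.12 to 0.19 (camera, adjusted p = 0.936), and the list mean was -0.14 in KO pool 1 and 0.20 in KO pool 2. By fry's mixed test, which asks whether members change in either direction, the list passed (adjusted p = 0.0383), as did 10 of the 20 lists that camera did not call, this one and de novo lipogenesis (adjusted p = 0.0357) included. Mlkl, the executor of necroptosis, was at 0.79 ± 0.24 SE, Casp12 at 0.83 ± 0.23 and Pmaip1 at 0.66 ± 0.19. Ripk3 was at 0.02 ± 0.19 and Cflar, the inhibitor of caspase 8 activation, at -0.42 ± 0.21, or -0.27 without KO pool 1. None of these passed adjusted over the list alone. The sign of Ripk3 turned under quantile normalization and median centring, without WT pool 2 (-0.03) and without KO pool 2 (-0.01). Its WT and KO means lay 0.10 and 0.12 above the table median, where a fall may not be seen.

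De novo lipogenesis genes had a median difference of 0.00 over 24 members (interval -0.15 to 0.05; camera, adjusted p = 0.5). Lpin1, a phosphatidate phosphatase and transcriptional coactivator, was lower adjusted over the list alone, at -1.56 ± 0.21 SE, while Elovl6 was at 0.49 ± 0.19, Fasn at 0.45 ± 0.21 and Acaca at 0.31 ± 0.20, or 0.17 without KO pool 2. Lipid droplet and uptake genes had a median of 0.09 (adjusted p = 0.809), with Cidec at 0.67 ± 0.23 and Cidea at -0.74 ± 0.28, or -0.44 without KO pool 1. The median of the list named for the epidermal growth factor family and ErbB receptors was 0.03 over 16 members (camera, adjusted p = 0.551). It turned sign in 5 alternatives, and with genes above the upper quartile of the table the list passed as lower (median -0.29, adjusted p = 0.041). Egfr was lower adjusted over the list alone, at -1.08 ± 0.22. Erbb3 was at -0.09 ± 0.21, a sign that turned under quantile normalization, without WT pool 2 (0.01) and without KO pool 1 (0.05), with -0.22 without KO pool 2. Erbb4 was at 0.38 ± 0.28, between 0.08 and 0.69 without 1 of the KO pools.

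**Figure D3:**
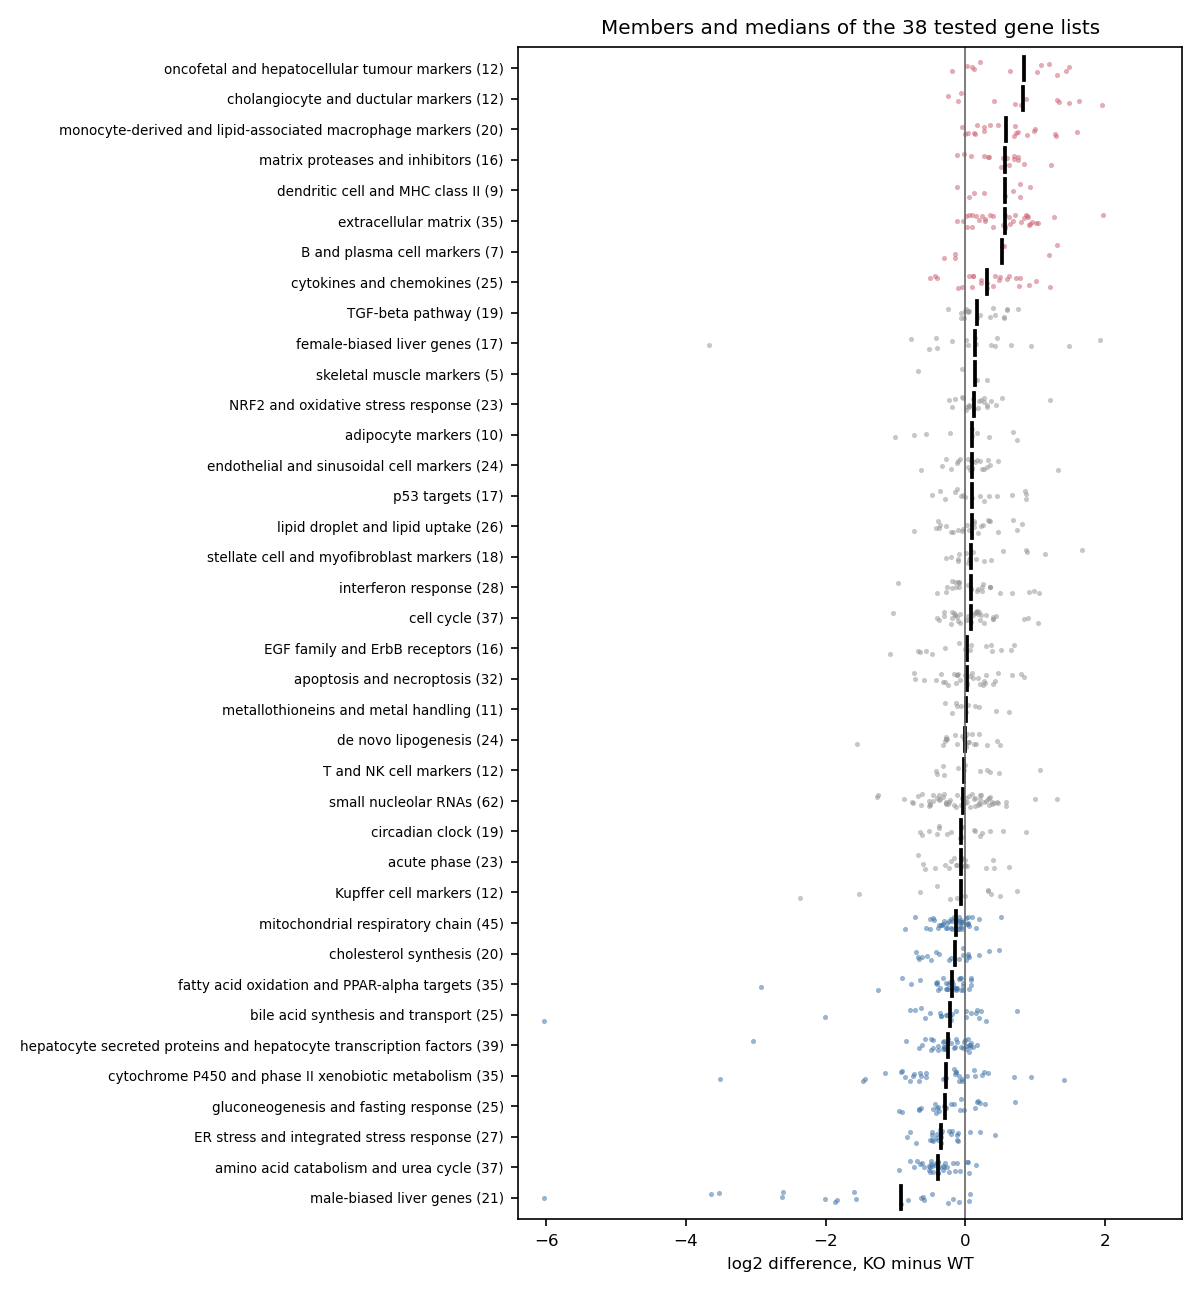
Log2 difference between KO and WT (x axis) for each member (points) and the median (black bar) of the 38 tested gene lists, with the number of measured members in brackets. Red and blue lists passed camera with the preset correlation as higher (8 lists) or lower (10 lists) in KO, grey lists did not, and none passed with an estimated correlation.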

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

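The number of genes called depended on the variance model and on having all 4 pools. Leaving out a pool also leaves fewer residual degrees of freedom. Calls lost that way therefore do not tell lost power from an effect of the pool left out. The medians of the 18 called lists kept their sign under each alternative run. Only the filters, the normalizations, the mean of probe sets, left-out members and left-out pools could change a median. The variance models, the block and the set tests reuse the main medians. The single alternative chosen after seeing the data is the one without members shared with the male-biased list. With a variance that follows intensity, 49 genes were higher and 87 lower by limma; with the replicate number as a block, 0 higher and 2 lower passed (1213 genes at an unadjusted p under 0.05). The replicate numbers did not deviate together (r = -0.04 across genes), so the block is no pairing. With the block the TGF-beta list passed (adjusted p = 0.0449, range 0.0136 to 0.48 over its alternatives). Testing all 41345 probe sets gave 0 higher and 0 lower (2671 at an unadjusted p under 0.05). An unadjusted p under 0.05 with a 1.5-fold change gave 664 higher and 387 lower. Without 1 pool, where the lone pool is assumed to vary like the other group, both counts were 0 for each of the 4 pools, with 987, 1314, 993 and 906 genes at an unadjusted p under 0.05 without KO pool 1, KO pool 2, WT pool 1 and WT pool 2. The remaining alternatives (filters, normalizations, robust variance, mean of probe sets, adjusted p under 0.10, limma treat) left 2 to 4 genes in each direction. Nrg4 lay between -1.60 and -1.37 under each alternative it was run under and kept an unadjusted p under 0.05. Of the 18 lists called, camera with an estimated correlation called 0 and fry 1; the medians of the matrix list (0.565) and the macrophage list (0.578) are the same there, with adjusted p of 0.227 by camera and 0.061 by fry. The simulated shift of 0.5 was missed in every simulation by camera with an estimated correlation, with 2 residual degrees of freedom. Those simulations drew genes independently, so they do not settle which correlation applies to the data. The other alternatives called 15 to 20 lists. The intensity-dependent and robust variance models did not enter camera, so their 18 calls are those of the main run. The median of the EGF family list turned to -0.285 (adjusted p = 0.041, range 0.041 to 0.961 over its alternatives) among genes above the upper quartile of the table; the cause was not tested. The B and plasma cell list lost its call under 7 of the alternatives other than these set tests. Leaving out members shared with the male-biased list gave 18 calls, with the bile acid list at an adjusted p of 0.0286 (range 0.000599 to 0.48 over its alternatives). Median, mean and test differed in sign for the lipogenesis, EGF family, T and NK cell, adipocyte, skeletal muscle and metallothionein lists, none of which was called. No depth is recorded for arrays. Dim genes near the table median (0.54) may have compressed folds, which was not measured.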

Other observations

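The tests of the hepatocyte share, the female pattern, the stellate cells and the splits of the list counts were chosen after the results were seen. Kupffer cells, the resident macrophages of the liver, did not pass as a list (median -0.07 over 12 markers, camera, adjusted p = 0.353), and the median turned sign in 3 alternatives, to 0.33 among genes above the upper quartile of the table. In the list, 2 scavenger receptors stood apart. Marco differed by -2.37 ± 0.33 (SE) and Cd163 by -1.53 ± 0.23, both lower when adjusted over the list alone, while Vsig4 and Clec4f, chosen after their values were seen, were at -0.01 and 0.33. B and plasma cell markers were called by camera (median 0.52 over 7 members, adjusted p = 0.0383; adjusted p = 0.403 with an estimated correlation). Of these members 4 were higher and 3 lower, and the bootstrap interval of the median over genes was -0.16 to 1.19. Ighm, the heavy chain of IgM, was at 1.32 ± 0.19 (0.77 as the mean of its probe sets) and Jchain at 1.19 ± 0.26, both higher when adjusted over the list alone. The call was lost without WT pool 1 (adjusted p = 0.107), without KO pool 1 (0.146) and without KO pool 2 (0.0621). It was also lost with no filter on dim genes (median 0.04, adjusted p = 0.217), quantile normalization (0.0642), the mean of probe sets (0.0605) and ranks (0.249), with a range of 0.0339 to 0.403 over its alternatives. Neutrophil markers were too dim to test, with 3 of 16 above the filter.

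Other lists did not pass camera. The p53 targets had a median of 0.09 (adjusted p = 0.248), with Cdkn1a at 0.87 ± 0.24 (SE), and passed without WT pool 2 (median 0.34, adjusted p = 0.0285, range 0.0285 to 0.898 over its alternatives). The NRF2 list had 0.13 (0.0844, past the threshold under 3 alternatives), the acute phase list -0.06 (0.205), the interferon list 0.08 (0.457), the cell cycle list 0.08 (0.457), and metal handling 0.00 (0.964). The circadian clock list was at -0.06 (0.457), with Npas2 at 0.87 ± 0.23 and Nr1d1 at 0.54 ± 0.19. Adipocyte markers were at 0.09 (0.964), skeletal muscle markers at 0.13 (0.809) and small nucleolar RNAs at -0.04 (0.213). Over the members on the array, the untested neutrophil, pancreatic and erythroid lists had medians of -0.05, -0.01 and -0.09. The Y-linked gene Eif2s3y lay between 5.28 and 5.88 in the 4 pools and Xist between 0.07 and 0.53, below the table median of 0.54; both were chosen as a check of the male labels after the main results were seen.

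Intervals here and below are bootstrap 95% intervals over genes, which are not replicates. The fall of the male-biased list may reflect fewer hepatocytes, a shift toward the female pattern, or a wider change of the diseased hepatocyte. The male-biased median lay 0.67 below that of the hepatocyte list (difference -0.67, interval -1.72 to -0.30). The difference was below 0 in each of 7 settings, which are the filters on dim genes and each pool left out. These settings reuse the same pools. The male-biased list was picked for its fall, so a gap was built in. The comparison therefore does not decide whether a lower share of hepatocytes was the whole cause. A shift toward the female pattern stays open. The female-biased list had a median of 0.13 (interval -0.40 to 0.45), with members that went both ways, so it decides nothing. Loss of Nrg4 acting on the hepatocyte, directly or through the severity of disease, was not tested.

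The rise of matrix, macrophage and ductular lists could come from fewer hepatocytes or from more stellate cells alone. A lower share of hepatocytes should raise all other cells alike. These lists together lay 0.54 above the endothelial and Kupffer cell lists (interval 0.28 to 0.74, above 0 in each of the same settings). Against the endothelial list alone the gap was 0.53 (interval 0.27 to 0.70). The lists on one side were chosen for their rise and the others after their values were seen, so a gap was built in. The test therefore does not decide whether fewer hepatocytes were the cause. The matrix list lay 0.48 above the stellate cell list (interval 0.09 to 0.68), but the interval included 0 with genes above the upper quartile of the table (-0.01 to 0.85), without WT pool 1 (-0.06 to 0.76) and without KO pool 1 (-0.10 to 0.71). More stellate cells and activation within them therefore stay open, as do fewer hepatocytes and the KO genotype itself.

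The differences between KO and WT could also stem from a chromosome segment linked to the disrupted gene, or from chance. Differences of genetic background elsewhere in the genome were not tested. Of the genes at an unadjusted p under 0.05, 1.33% lay among the 100 measured genes on each side of Nrg4. Of these 200 neighbours, 8.5% had such a p, against 10.3% of the other genes (one-sided Fisher's exact test, p = 0.83). The neighbours thus held no excess of such genes. Since 200 neighbours cannot hold most of 1282 such genes, the 1.33% decides nothing. Effects of the segment on genes elsewhere were not tested. The 4 arrays allow 3 splits, too few for a share under 0.05. The real split gave 6 genes past the adjusted threshold and 18 lists, the highest other split gave 0 of each, and in both cases 1 of 3 splits, the real one, reached that value. With a variance that follows intensity the real split gave 136 genes and the others 0. The other splits mix WT and KO pools in each group, so differences of genotype enter their residual spread and lower their counts. They gave 336 and 470 genes at an unadjusted p under 0.05 by limma, against 622.9 expected by chance. The contrast between the splits therefore does not exclude chance.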
